A study of Homo sapiens with 6 samples.

How the data were processed

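RNA was measured by sequencing in 6 samples of SNU-387, an established human hepatocellular carcinoma line. Per the labels, 3 samples come from cells that stably carry a non-target short hairpin RNA (shNT) and 3 from cells that stably carry a hairpin against YES1 (shYES1). Per the labels' protocols, RNA was extracted with Trizol and a Qiagen column, and libraries were made from poly(A) RNA with a KAPA stranded kit. The labels do not say whether the 3 samples of a group were grown as separate cultures, so the p-values measure the spread between these samples, which may be technical. The hairpin sequence and the number of hairpins used are not given in the sources used here.

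The deposited values are read counts per gene, whole numbers with no normalization, in 1 file per sample with a column for unstranded counts and a column for each strand. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Trimmomatic 0.35 and STAR 2.5.1b with genome build GRCh38. The annotation release behind the counts is not given in the sources used here. The counts of the reverse-strand column were used, because 93.5% to 94.0% of the stranded gene reads of each library fell on it. Each file lists 58219 gene identifiers and 4 entries that name no gene (unmapped, multimapping, without a feature, ambiguous), which held 19.8% to 20.3% of the reads and were left out of library sizes and tests. Of the 58219 identifiers, 57392 were matched to symbols and 57881 are in GENCODE release 29 on GRCh38, from which coordinates and gene types come. A read that maps equally well to several places is not counted for any gene, so near-identical copies can lose reads, and genes whose exons overlap on the same strand can lose reads as ambiguous. Values of such genes are uncertain. Among genes given in the report, exons of ERLIN1, FADS2, HIF1A, MMP2, SAA2, SDHD, CXCL6, TIGAR, MCL1, COL3A1, RPS3 and SLC16A3 overlap another annotated gene on the same strand, in several cases a small noncoding RNA.

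Gene reads numbered 12825919, 13651401 and 16388822 in shNT samples 1 to 3, and 15975170, 11290889 and 18944148 in shYES1 samples 1 to 3. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, minimum total count 15) kept 14239 genes, TMM factors scaled the libraries, and the quasi-likelihood test with robust dispersion compared shYES1 with shNT. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic, which is approximate. Normalised read counts are CPM values (each gene's reads scaled to a common library total after TMM scaling), computed from the deposited counts, and are given as mean ± SD with n = 3 libraries per group. The common biological coefficient of variation was 2.10%.

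Before the data were examined, 36 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The rule names YES1 and the tested members of the SRC family, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, and up to 3 rises and 3 falls per list, with clone-based names, pseudogenes and read-through names left out of the largest changes. Where fewer than 2 members of a list pass, the most highly expressed members are given as values. Not every gene that the rule names is reported here. Each list with at least 5 tested members (34 of the 36) was tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and adjustment over the lists. Each was also tested with an estimated correlation and with fry, which asks whether the members move in 1 direction on balance and compares them with no other genes. Counts of list members past the threshold are over all genes tested, and those adjusted over the list alone are given where they differ.

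Alternatives were RLE or library-size scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a filter at 1 CPM in 3 libraries, the sample number as a block, and leaving out each library in turn. Unstranded counts, scaling on genes without a sequence found in the 3' UTR scan, testing those genes only and a test against a change of 1.2-fold were chosen after seeing the data. In counts simulated from these libraries (14015 genes tested), the edgeR step recovered 54.2% of genes changed by 0.25 on the log2 scale, 87.8% at 0.5, 97.8% at 1 and 100% at 2, with 2.99% false calls. DESeq2 recovered 41.7%, 79.6%, 89.1% and 97.9% at those sizes. Each size was given to only 46 to 49 tested genes, far fewer than changed in the data, so recovery in the data can differ.

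The 3' UTR scan used the annotated 3' UTRs of at least 50 bases of 11906 tested genes and asked, for each of 16123 sequences of 7 bases present in at least 30 genes, whether genes with the sequence differed in log2 fold change, limited to 3 in either direction. The sequence was chosen on odd-numbered chromosomes and tested on the others. Scans, intervals and comparison sequences were run in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The files carry no sequencing batch or date, and no batch was modelled.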

Results

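The transcriptome of SNU-387, a cell line from a pleomorphic hepatocellular carcinoma, was measured by stranded poly(A) RNA sequencing after stable expression of a short hairpin RNA. A short hairpin RNA is processed in the cell into a small RNA that silences transcripts it pairs with. The design asks how gene expression in these liver cancer cells differs when YES1, a tyrosine kinase of the SRC family, is lowered. The control group carried a non-target hairpin (shNT, n = 3) and the other group a YES1 hairpin (shYES1, n = 3). Between 11290889 and 18944148 reads per library were assigned to genes. Samples of a group correlated at 0.994 to 0.996 across genes (Pearson, log2 CPM) and samples of different groups at 0.969 to 0.970, where genes are not independent replicates. The first principal component held 80.7% of the variance and separated the groups. The 10 most abundant genes took 9.35% to 9.84% of gene reads in shNT and 7.55% to 7.98% in shYES1. Replicates of each group differed by more than sampling noise, with a chi-square per degree of freedom of 1.15 to 2.20, so no library was counted as a duplicate.

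In shYES1 cells, YES1 RNA was 4.06-fold lower than in control cells, and a broad set of genes changed with it. All tested genes of the G1/S and G2/M lists were lower, as were most NF-kB and inflammatory cytokine genes and most glycolysis and hypoxia genes. Genes of cholesterol and fatty acid synthesis were mostly higher. ADAM9, a membrane protease, showed the largest fall among the genes singled out for size, and NDRG4 the largest rise. Listed targets of YAP and TAZ, the transcriptional coactivators that SRC-family kinases can activate, moved in both directions.

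YES1 (ENSG00000176105.13, GRCh38 chromosome 18, 721588 to 812546, minus strand) fell from 179.5 ± 1.65 CPM in shNT to 44.1 ± 1.70 CPM in shYES1. Its log2 fold change was -2.02 (SE 0.037, edgeR adjusted p = 7.93e-40), and every shYES1 library lay below every shNT library. Of the 8 other listed SRC-family kinases, 4 were expressed enough to test and all 4 were lower in shYES1. SRC fell from 54.0 ± 3.36 to 35.9 ± 1.88 CPM (log2 fold change -0.60) and FYN from 66.4 ± 0.182 to 54.5 ± 1.35 CPM (-0.29). FRK fell from 13.5 ± 1.69 to 8.55 ± 0.752 CPM (-0.66). LYN fell only slightly, from 30.7 ± 1.02 to 27.8 ± 2.14 CPM (-0.14, edgeR adjusted p = 0.0349). That call was lost under library-size scaling (adjusted p = 0.508), with DESeq2 (0.152), without a low-count filter (0.113), without shNT sample 2 (0.124), without shYES1 sample 1 (0.272, log2 fold change -0.08) and against a 1.2-fold minimum. With 4 tested members the SRC-family list was too short for the list test.

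**Figure D1:**
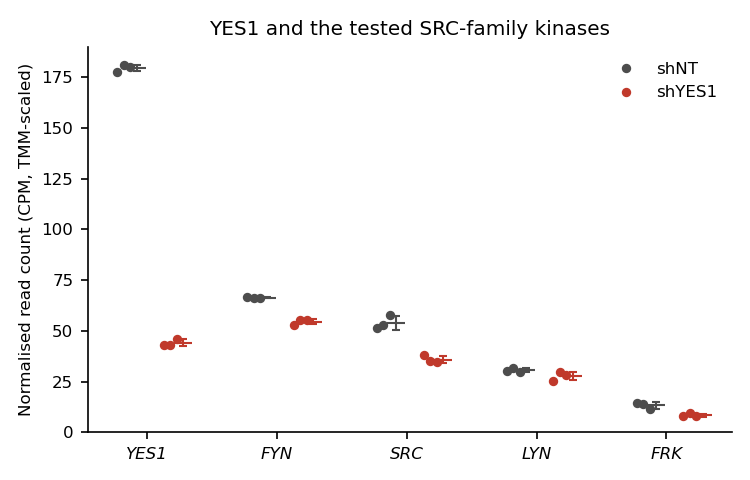
Normalised read counts (CPM) of YES1 and 4 SRC-family kinases in each library, as points, with the group mean as a dash and its SD as a bar (n = 3 per group). YES1 lies near 179.5 CPM in shNT and near 44.1 CPM in shYES1, and the other 4 kinases differ by much less.

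Across the 14239 genes tested, 9299 (65.3%) passed an edgeR adjusted p of 0.05, 4623 higher and 4676 lower in shYES1. The changes were mostly small, with a median of 1.35-fold among called genes. At 2-fold or more the calls were unequal, with 356 genes higher and 886 lower. A test against a minimum change of 2-fold called 629 genes, 123 higher and 506 lower, and a test against 4-fold called 5 higher and 47 lower. The groups did not overlap for 67.9% of genes, where chance gives 10%. Scaling moves the balance of the calls: with library size only, 5799 genes were higher and 3762 lower, and with scaling on genes that lack the 3' UTR sequence CCTTTC, 3580 were higher and 5671 lower. The median log2 fold change of all genes was -0.00469 with TMM, 0.0921 with library size only and -0.094 with the latter scaling.

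**Figure D2:**
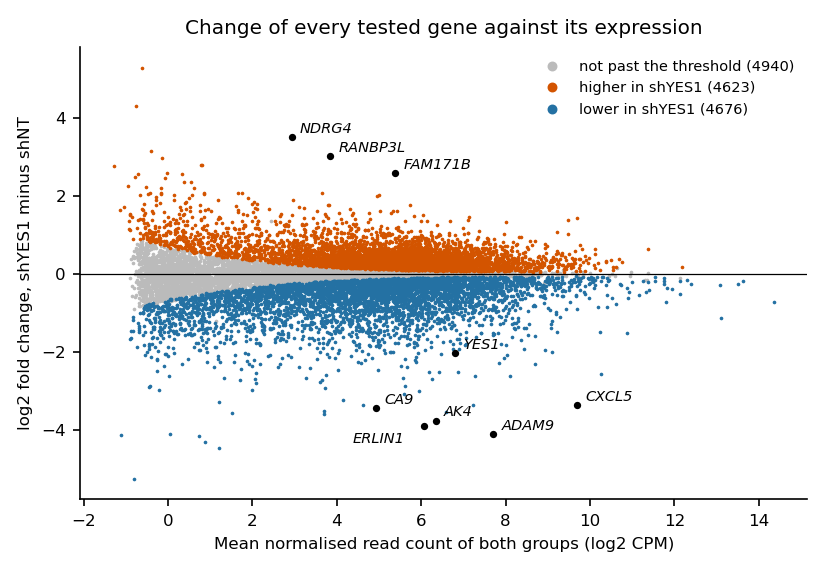
Log2 fold change (shYES1 minus shNT) of each of the 14239 tested genes against its mean normalised read count in log2 CPM, with genes past an adjusted p of 0.05 in colour and named genes in black. Of the genes in colour, 4623 lie above and 4676 below the line. The largest falls reach further than the largest rises among well expressed genes.

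Among called genes with a mean of at least 5 CPM and no overlap between groups, the 10 largest falls ranged from 17.3-fold to 10.3-fold. ADAM9 (ENSG00000168615.11, chromosome 8, 38996869 to 39105144), which sheds membrane-bound proteins, fell from 395.6 ± 5.54 to 22.8 ± 0.907 CPM (log2 fold change -4.12, SE 0.0382, edgeR adjusted p = 9.07e-52). ERLIN1 (chromosome 10, 100150094 to 100188334), a membrane protein of the endoplasmic reticulum, fell from 124.9 ± 2.01 to 8.41 ± 0.715 CPM (-3.91), though its exons overlap those of CHUK on the same strand. AK4 (chromosome 1, 65147549 to 65232145), a mitochondrial adenylate kinase, fell from 151.7 ± 3.97 to 11.3 ± 1.05 CPM (-3.76). CXCL5 (chromosome 4, 73995642 to 73998779), a neutrophil-attracting chemokine, fell from 1506 ± 20.03 to 146 ± 2.70 CPM (-3.37). SDCBP, the adaptor protein syntenin, fell from 274 ± 7.70 to 26.5 ± 2.01 CPM (-3.37), and HAPLN1, which links hyaluronan to proteoglycans, from 176 ± 12.02 to 15.2 ± 1.07 CPM (-3.54). CA9, a carbonic anhydrase induced by low oxygen, fell from 55.9 ± 6.18 to 5.06 ± 0.557 CPM (-3.45). TLCD3A (-3.59), the acute-phase gene SAA2 (-3.52) and the chemokine CXCL6 (-3.37) complete the group. SAA2 shares sequence and exons with neighbouring SAA genes and CXCL6 resembles CXCL5, so their levels are uncertain.

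The 10 largest rises chosen in the same way were smaller, from 11.5-fold to 3.40-fold. NDRG4 (ENSG00000103034.14, chromosome 16, 58462846 to 58513628) rose from 1.23 ± 0.221 to 14.0 ± 0.0887 CPM (log2 fold change 3.53, SE 0.148, edgeR adjusted p = 1.66e-25). RANBP3L (chromosome 5, 36248434 to 36302114) rose from 3.18 ± 0.269 to 25.5 ± 1.73 CPM (3.02) and FAM171B (chromosome 2, 186693971 to 186765965) from 12.1 ± 1.89 to 71.5 ± 5.09 CPM (2.58). The amino acid transporter gene SLC7A7 (2.08), the microtubule-associated protein gene MAP1A (2.02) and the surface glycoprotein gene THY1 (2.0) each rose about 4-fold. The chemokine CX3CL1 (1.89), PGM2L1 (1.78), the lipase gene LIPH (1.77) and the arginase gene ARG2 (1.76) followed. For all 20 genes the groups are separate by the choice itself, since only called genes with no overlap between groups were eligible. Each kept its call and direction under every alternative run for it.

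**Figure D3:**
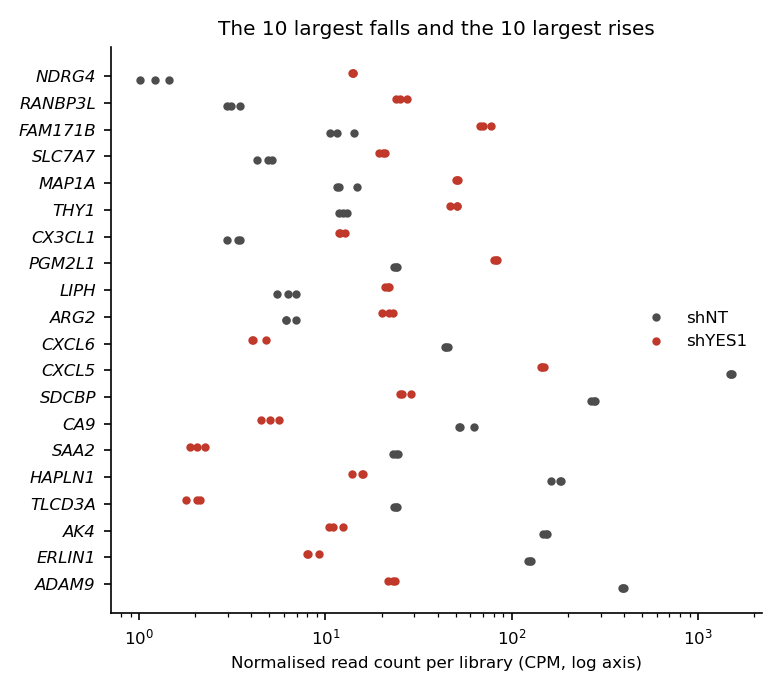
Normalised read count (CPM, log axis) of each library for the 10 largest falls and 10 largest rises among genes with a mean of at least 5 CPM, with a point per library and a colour per group (n = 3 per group). Only called genes with no overlap between groups were eligible, so the groups are separate for all 20 genes. Means run from NDRG4 at 1.23 against 14.0 CPM to ADAM9 at 395.6 against 22.8 CPM.

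Genes of the cell division cycle were lower throughout. All 34 tested genes of the G1/S and DNA replication list fell, with a median log2 fold change of -0.99 and 17 of them at least 2-fold lower. TYMS, which makes thymidylate for DNA synthesis, fell from 97.6 ± 5.23 to 20.7 ± 2.81 CPM (-2.27), the cyclin gene CCNE2 from 5.77 ± 0.763 to 1.35 ± 0.502 CPM (-2.02), and MCM2, a subunit of the replicative helicase, from 48.5 ± 2.48 to 14.2 ± 1.09 CPM (-1.76). All 34 genes of the G2/M and mitosis list fell as well (median -0.86), among them the spindle motor gene KIF11 (-1.43), the phosphatase gene CDC25C (-1.38) and the topoisomerase gene TOP2A, from 449 ± 1.28 to 174 ± 5.48 CPM (-1.37). Both lists moved down against all other genes (camera adjusted p = 7.79e-13 for G1/S and 2.71e-18 for G2/M). With an estimated correlation the adjusted p was 0.0665 for G1/S and 0.0853 for G2/M. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, gave 5 higher and 2 lower of 9 tested (camera adjusted p = 0.366), such as H2BC4 (0.89) and H2BC12 (0.35).

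The p53 target list was not called (camera adjusted p = 0.207) but held large single changes. Of 24 tested members 14 rose and 5 fell, and adjusted over the list alone 16 rose and 5 fell. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 34.1 ± 1.18 to 98.1 ± 3.48 CPM (1.52), and TIGAR (0.81) and AEN (0.77) rose. CCNG1, encoding cyclin G1, fell from 123 ± 2.68 to 21.4 ± 0.891 CPM (-2.53) and the death receptor gene TNFRSF10B fell (-0.81). Of 13 BCL2 family genes 9 rose and 2 fell (median 0.31, camera adjusted p = 0.0375), with the killer gene BAK1 at 0.94, the survival gene BCL2L1 at 0.58 and BCL2L11, which encodes the killer protein BIM, at 0.58. With an estimated correlation that list's adjusted p was 0.409, and among genes without CCTTTC in the 3' UTR its call was lost (median 0.15, adjusted p = 0.876).

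Inflammatory genes formed another group that fell. In the NF-kB and inflammatory cytokine list 20 of 23 genes fell, 1 rose and 2 did not pass (median -0.89, camera adjusted p = 1.88e-10). With an estimated correlation the adjusted p was 0.0606. The chemokine genes CXCL5 (-3.37), CXCL1, from 478 ± 9.89 to 77.8 ± 3.24 CPM (-2.62), and CCL20 (-2.93) fell most, and TNFAIP2 rose (0.13). The call of TNFAIP2 was lost when scaled on genes without CCTTTC in the 3' UTR and in the 1.2-fold test. The STAT3 response list had 9 genes lower, 2 higher and 4 that did not pass (median -0.19, camera adjusted p = 0.00282, and adjusted p = 0.192 with an estimated correlation). Its median was -0.28 without shNT sample 3. In the list the cytokine genes IL6, from 175 ± 6.59 to 55.2 ± 2.89 CPM (-1.68), and LIF (-1.46) fell, and SOCS3, which restrains STAT3 signalling, rose (0.26). Interferon-stimulated genes split, with 9 of 28 higher and 10 lower (camera adjusted p = 0.793). OASL (1.36) and RIGI (0.61) rose while OAS2 (-1.20) and PARP9 (-0.56) fell.

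Energy metabolism moved in opposite directions. Of 30 glycolysis and hypoxia genes 27 fell and 3 rose (median -0.90, camera adjusted p = 7.59e-14, and adjusted p = 0.192 with an estimated correlation). Besides CA9, the vasoactive peptide gene ADM fell from 53.9 ± 4.38 to 9.54 ± 1.08 CPM (-2.47) and the collagen prolyl hydroxylase gene P4HA1 from 379 ± 12.6 to 77.7 ± 0.845 CPM (-2.29). PFKM (1.0), HK1 (0.59) and the lactate exporter gene SLC16A3 (0.29) rose. HIF1A, the oxygen-regulated transcription factor of this response and a member of the STAT3 list, fell from 878 ± 17.1 to 312 ± 8.76 CPM (-1.49), with a short overlapping transcript annotated on its strand. In the oxidative phosphorylation list 20 of 34 genes rose and 3 fell (median 0.16, camera adjusted p = 0.00853, and 0.309 as adjusted p with an estimated correlation). Among genes without CCTTTC in the 3' UTR that call was lost, with a median of 0.24 (adjusted p = 0.0657). SDHB rose from 62.5 ± 2.79 to 103 ± 1.64 CPM (0.72) and NDUFA4 rose (0.59), while SDHD, of the same complex as SDHB, fell (-1.84) and overlaps another annotated gene. Among the 13 genes encoded by the mitochondrial genome, 5 fell and 8 did not pass, and 2 fell when adjusted over the list alone (median -0.14, camera adjusted p = 0.0375, and 0.675 as adjusted p with an estimated correlation). Without shNT sample 2 that median was -0.22. The mitochondrial call was lost under library-size scaling (adjusted p = 0.172), with fry (0.101), without shNT sample 3 (0.0963), without shYES1 sample 2 (0.0921) and without shYES1 sample 3 (0.0616).

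**Figure D4:**
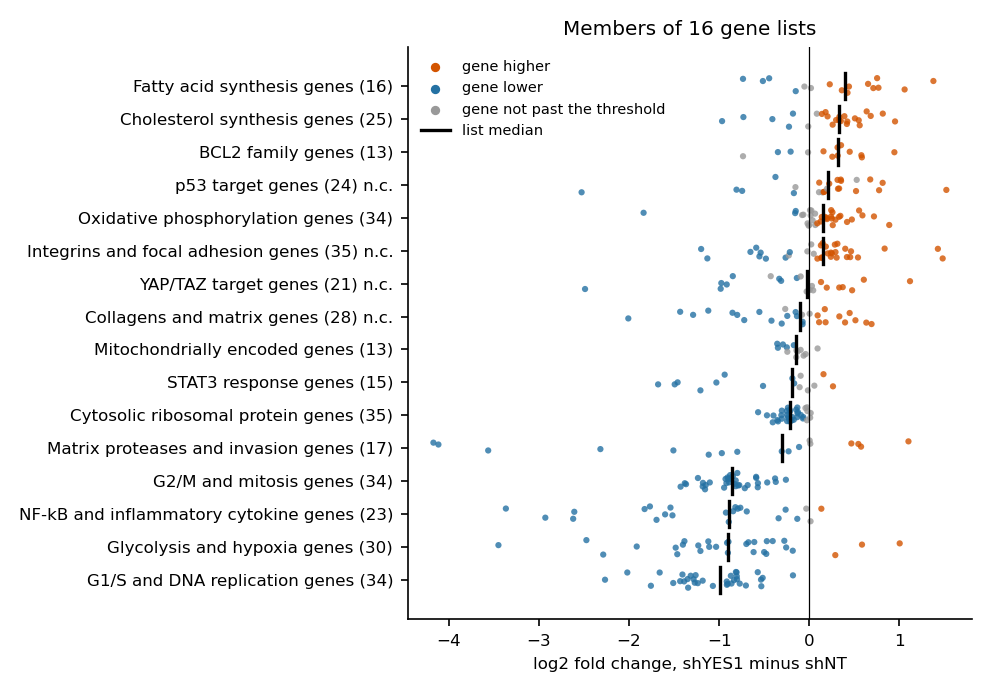
Log2 fold change (shYES1 minus shNT) of every tested member of 16 gene lists, a point per gene coloured by its call, with the list median as a black tick and the number of tested members in parentheses. Lists marked n.c. were not called by camera, and the G1/S list has the lowest median (-0.99) and the fatty acid list the highest (0.39).

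Lipid synthesis genes were mostly higher. Of 25 cholesterol synthesis genes 18 rose and 5 fell (median 0.33, camera adjusted p = 0.00235, and 0.263 as adjusted p with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose from 224 ± 11 to 434 ± 10.4 CPM (0.95), and MSMO1 (0.82) and MVD (0.68) rose. DHCR7, which catalyses the last step to cholesterol, fell from 288 ± 2.22 to 148 ± 4.33 CPM (-0.97), and INSIG1, which restrains the pathway, fell (-0.73). Of 16 fatty acid synthesis genes 10 rose and 4 fell (median 0.39, camera adjusted p = 0.00853, and 0.192 as adjusted p with an estimated correlation). FASN, the fatty acid synthase, rose from 399 ± 25.5 to 1036 ± 23.7 CPM (1.38), ACSS2 from 89.9 ± 4.62 to 187 ± 1.44 CPM (1.06) and ACLY from 229 ± 2.58 to 390.4 ± 2.04 CPM (0.77). ME1 (-0.74) and FADS2 (-0.51), whose exons overlap FEN1, fell.

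Genes of the matrix and of adhesion went both ways. The matrix protease and invasion list was lower, with 11 of 17 genes down and 4 up (median -0.31, camera adjusted p = 0.0305, and 0.417 as adjusted p with an estimated correlation). Its median was -0.56 without shNT sample 1 and -0.52 without shYES1 sample 2. Besides ADAM9, the collagenase gene MMP1 fell from 5.29 ± 0.068 to 0.440 ± 0.172 CPM (-3.56), and S100A4 rose from 34.4 ± 2.76 to 73.9 ± 2.17 CPM (1.1). This call was lost among genes without CCTTTC in the 3' UTR (median -0.05, adjusted p = 0.461). Collagen and matrix genes gave 15 lower and 10 higher of 28 (camera adjusted p = 0.209), with the crosslinking enzyme gene LOX, from 878 ± 19.9 to 218 ± 3.48 CPM (-2.01), and COL3A1 (-1.29) lower and THBS1, from 2093 ± 48.6 to 3245 ± 69.7 CPM (0.63), higher. TGF-beta response genes gave 11 lower and 7 higher of 21, or 12 and 8 adjusted over the list alone (median -0.16, camera adjusted p = 0.18, fry adjusted p = 1.4e-07, lower). Among genes without CCTTTC in the 3' UTR the direction of that list turned (median 0.36, camera adjusted p = 0.461). MMP2, a gelatinase, fell from 2111 ± 15.98 to 356 ± 13.0 CPM (-2.57), with another transcript annotated over its exons, while ID1 rose (0.82). Of 35 integrin and focal adhesion genes 22 rose and 9 fell, or 23 and 9 adjusted over the list alone (median 0.15, camera adjusted p = 0.0571). ITGA5, the fibronectin receptor subunit, rose from 449.6 ± 8.21 to 1209 ± 38.7 CPM (1.43), and ITGA6, a laminin receptor subunit, fell from 434 ± 4.6 to 198 ± 1.56 CPM (-1.13). The integrin list passed the threshold under library-size scaling (adjusted p = 0.0348), without a low-count filter (0.00051), without shNT sample 1 (0.0369), without shNT sample 2 (0.0424) and with fry (0.00733).

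YAP and TAZ targets changed in both directions. Of 21 tested 7 rose, 8 fell and 6 did not pass, or 7 and 9 adjusted over the list alone (median -0.03, mean -0.20, camera adjusted p = 0.749). Against no other genes, fry placed the list lower on balance (adjusted p = 0.001). With a library left out its median ranged from -0.06, without shNT sample 3, to -0.01, without shYES1 sample 2. ANKRD1 fell from a low level of 1.43 ± 0.329 to 0.234 ± 0.153 CPM (-2.49), IGFBP3 from 109 ± 5.59 to 55.1 ± 1.62 CPM (-0.98) and LATS2 from 36.1 ± 2.0 to 18.2 ± 1.39 CPM (-0.98). NUAK2 rose from 9.02 ± 0.912 to 19.6 ± 1.24 CPM (1.12), and CRIM1 (0.61) and GADD45A (0.48) rose. Hippo pathway components gave 9 higher and 11 lower of 24 (camera adjusted p = 0.912), with the transcription factor gene TEAD3 at 0.67 and the kinase gene STK3 at 0.53 against WWC1 at -0.90 and MOB1A at -0.83. The ERK and growth factor response list gave 11 higher and 8 lower of 25, or 11 and 9 adjusted over the list alone (camera adjusted p = 0.79). Its ligand genes parted: EREG rose from 106 ± 2.08 to 226 ± 4.93 CPM (1.1) and AREG fell from 16.02 ± 1.02 to 5.12 ± 0.965 CPM (-1.63), with EGR1 also lower (-1.63). Receptor tyrosine kinase genes gave 10 higher and 5 lower of 20 (camera adjusted p = 0.156), with PDGFRB (1.33) and ROR1 (1.11) up and FGFR4 (-1.59) and ROR2 (-0.92) down. Among genes without CCTTTC in the 3' UTR, that list passed the threshold (median 1.02, adjusted p = 0.00263). Notch pathway genes gave 3 higher and 4 lower of 11 (camera adjusted p = 0.888), with the ligand gene JAG1 up from 57.8 ± 0.219 to 149 ± 3.57 CPM (1.36) and the receptor gene NOTCH2 down from 404 ± 21.4 to 114 ± 1.71 CPM (-1.82). WNT/beta-catenin targets gave 4 higher and 5 lower of 16 (camera adjusted p = 0.912), including BAMBI (1.34) and MYC (-0.76).

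Stress and biosynthesis lists showed changes in both directions. The cytosolic ribosomal protein list was lower, with 29 of 35 genes down and 0 up (median -0.21, camera adjusted p = 7.25e-07, and 0.451 as adjusted p with an estimated correlation), led by RPL15 (-0.57) and RPS3 (-0.47). MYC and ribosome biogenesis genes gave 6 higher and 10 lower of 27, or 5 and 10 adjusted over the list alone (camera adjusted p = 0.288), with RRP9 (0.49) up and LYAR (-0.75) and ODC1 (-0.72) down. ATF4 and amino acid response genes gave 7 higher and 12 lower of 27, or 7 and 13 adjusted over the list alone (camera adjusted p = 0.0864). SHMT2, of mitochondrial serine metabolism, fell from 196 ± 6.81 to 69.6 ± 1.68 CPM (-1.50), the cationic amino acid transporter gene SLC7A1 fell (-2.0), and the glutamine transporter gene SLC1A5 rose (0.83). Endoplasmic reticulum chaperone genes gave 7 higher and 13 lower of 21 (camera adjusted p = 0.0864), with HSPA5 up from 915 ± 10.5 to 1296 ± 19.3 CPM (0.50) and CANX down from 1758 ± 8.35 to 974 ± 4.78 CPM (-0.85). These last lists and the TGF-beta and NRF2 lists passed the threshold without a low-count filter (adjusted p = 0.00937 for ATF4, 0.00197 for chaperones, 0.0177 for TGF-beta and 0.031 for NRF2). NRF2 targets gave 13 higher and 6 lower of 22 (camera adjusted p = 0.164), with AKR1B10 up from 19.8 ± 1.33 to 61.2 ± 2.36 CPM (1.62) and TXNRD1 down from 351 ± 7.53 to 154 ± 2.26 CPM (-1.19). The similar genes AKR1C1 (1.45) and AKR1C2 (1.18) rose, and reads they share could not be assigned. Lysosome and autophagy genes gave 13 higher and 9 lower of 24 (camera adjusted p = 0.477), such as TFEB (0.62) and SQSTM1 (-0.28).

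Few hepatocyte, endothelial and haematopoietic genes were expressed enough to test. Of 30 hepatocyte genes 5 were expressed enough to test, with 1 higher and 2 lower (camera adjusted p = 0.912), and SERPINA1, the most abundant of the 3 called, stood at 19.1 ± 1.34 CPM in shNT and 16.9 ± 1.17 CPM in shYES1. The call of SERPINA1 was lost without shNT sample 3 (edgeR adjusted p = 0.254), without shYES1 sample 1 (0.0816), without shYES1 sample 2 (0.149), and under 4 other alternatives. Of 9 liver stem and progenitor genes 1 rose and 4 fell (camera adjusted p = 0.366), with THY1 up and ANPEP (-0.56) and ALDH1A1 (-0.59) down. Epithelial junction and keratin genes gave 5 higher and 5 lower of 13, or 5 and 6 adjusted over the list alone (camera adjusted p = 0.912), with KRT8 up from 494 ± 3.54 to 721 ± 9.38 CPM (0.54) and the junction genes DSG2 (-1.40) and CLDN1 (-1.31) down. Mesenchymal genes gave 6 higher and 6 lower of 14 (camera adjusted p = 0.79), with PDGFRB up and FAP down from 127 ± 3.57 to 55.4 ± 1.65 CPM (-1.19). Of 13 endothelial markers 6 were tested, with 3 higher and 1 lower at low levels (camera adjusted p = 0.366), among them ROBO4 at 8.12 ± 0.875 and 14.2 ± 0.136 CPM. Of 15 haematopoietic markers 3 were tested, too few for the list test: CSF1R rose (0.86) and LAPTM5 (-0.27) and CD14 (-0.20) fell. Median, mean and test differ in sign for the Hippo, ERK, interferon, epithelial, mesenchymal, hepatocyte and WNT lists, none of which was called, and median and mean differ for the haematopoietic list. Of the lists that camera did not call, fry called 13: the YAP and TAZ, collagen, TGF-beta, liver stem, ATF4, chaperone and MYC lists as lower, and the ERK, integrin, lysosome, receptor tyrosine kinase, endothelial and histone lists as higher.

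Genes also differed by a sequence in their 3' untranslated region (3' UTR). The 8-base sequence ACCTTTCA was built from the 7-base sequences with the most negative effect over all searched genes. The values in this paragraph therefore describe the sequence and do not test it. The 492 genes with ACCTTTCA in the 3' UTR had a median log2 fold change of -0.31, and 19.9% of them fell at least 2-fold. Genes with ACCTTTC (1128 genes, median -0.20) or CCTTTCA (1248 genes, -0.17) but not the 8-base sequence were also shifted down. The 6499 genes without CCTTTC had a median of 0.09, and 3.92% of them fell at least 2-fold. In the 3 shYES1 libraries the median of the 492 genes was -0.30, -0.29 and -0.30 against the mean of shNT. Of the genes described above, ERLIN1, AK4, HIF1A, CCNG1, SLC7A1, ME1 and MCL1, a survival gene of the BCL2 family that rose (0.16), carry ACCTTTCA, and TLCD3A, HAPLN1, SDCBP, CXCL5, SRC, FRK, CCNE2 and KIF11 are among those that fell and carry a 7-base part of it. FAM171B, LIPH, BCL2L11 and KRT8, which rose, also carry a 7-base part. Of the 10 largest falls 6 carry a 7-base part, 2 of them the whole sequence, and of the 10 largest rises 2 carry a 7-base part. Among uncalled genes searched, 19.2% carry a 7-base part. ADAM9, CA9, TYMS and MCM2 carry no CCTTTC.

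**Figure D5:**
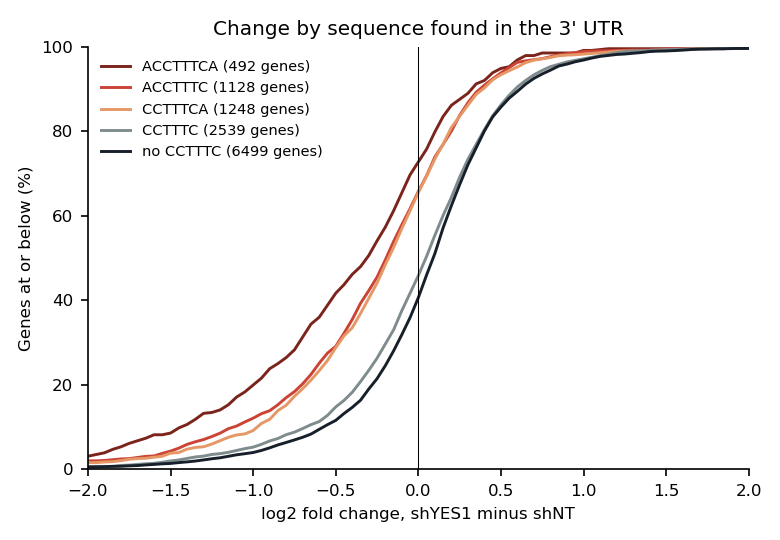
Percent of genes at or below each log2 fold change (shYES1 minus shNT), for genes grouped by the longest of the listed sequences in their 3' UTR. The curve of the 492 genes with ACCTTTCA lies furthest to the left (median -0.31) and that of the 6499 genes without CCTTTC furthest to the right at the median (0.09). The sequences were picked for their negative effect on these same log2 fold changes.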

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

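The tests of other splits of the samples, of scaling, of the falls-to-rises ratio without the sequence, of HIF1A and of oxygen or density were chosen only after the results were seen.

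Reads that fell on no annotated feature made up 7.31% of reads in shYES1 (7.27% to 7.39%) and 6.95% in shNT (6.67% to 7.22%), so every shYES1 library lay above every shNT library. Reads in more than 1 gene made up 2.67% in shYES1 (2.65% to 2.69%) and 2.60% in shNT (2.58% to 2.62%), again with no overlap. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real split) gave as many as 9299 changed genes, and the highest of the others gave 1 gene. The splits are too few for a share under 0.05.

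Many of the genes that fell at least 2-fold in shYES1 carry the sequence CCTTTCA in the 3' UTR, which was picked on odd-numbered chromosomes and ranked 1 of 16123 sequences on the other chromosomes. There, 33.1% of 348 fallen genes and 13.3% of 1605 uncalled genes had it (odds ratio 3.23, Fisher's exact test p = 1.11e-16, two-sided). The rank accounted for the length and GC content of the 3' UTR, and the Fisher test did not. CCTTTCA occurs in all 3 YES1 transcripts searched, though the 3' UTR searched for YES1 holds only CCTTTC. Of all sequences of 7 bases, 23.0% occur in at least 1 of those transcripts. A candidate explanation for part of these falls is therefore silencing of other transcripts through the seed of the YES1 hairpin's small RNA, whose sequence is not given in the sources used here. Whether such silencing accounts for all of them stays open. Of 735 fallen genes, 65.3% (Wilson 95% interval 61.8% to 68.7%) carry even CCTTTC, and 39.5% of uncalled genes carry it too. The other 255 fallen genes carry none in the annotated 3' UTR searched. The share of fallen genes lies under the 80% set in advance for nearly all, though above the 50% set for the opposite case. It therefore decides neither. The sequence picked in the same way for rises, TAATTTA, was not enriched among risen genes (odds ratio 0.925, Fisher's exact test p = 0.758).

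More genes fell than rose by at least 2-fold, 886 against 356, a ratio of 2.49. No scaling that was run removed this excess. The ratio was 1.64 under library-size scaling, the lowest of TMM, RLE and library size. It ranged up to 4.07 (267 higher, 1087 lower) when scaled on genes without CCTTTC. Because the ratio moved with the scaling, an offset between groups beyond those of the scalings run cannot be excluded. A trend with GC content or transcript length is argued against, since removing it left a ratio of 2.58. On the chromosomes not used to choose the sequence, the ratio among genes without CCTTTC was 1.47, below the 1.76 to 3.63 among genes without each of 100 other sequences of 6 bases, but it was 2.60 (others 2.93 to 6.74) when fold changes were centred on genes without CCTTTC. The ratio without CCTTTC lay below the 100 others under both centrings, but how much excess remained depended on the centring. Whether silencing through the seed accounts for the excess therefore stays open, as does lowering of YES1 itself. These cannot be told apart here, because every shYES1 sample has both a YES1 hairpin and lower YES1.

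Glycolysis and hypoxia genes fell in shYES1. Seed matches in the members themselves are argued against as the whole cause, because the 16 members without CCTTTC had a median log2 fold change of -0.61 (95% interval -1.11 to -0.26). That interval treats the members as independent, while the list's estimated correlation between genes was 0.239, so it is likely too narrow. Silencing of HIF1A through the ACCTTTCA in its 3' UTR is a candidate explanation: HIF1A was lower, with a log2 fold change of -1.49, but a change of HIF1A by another route would look alike, and these cannot be told apart. A difference in oxygen or cell density at harvest could also lower the list (median -0.90). Such a difference cannot be told apart from a hairpin effect, since every shYES1 sample carries a YES1 hairpin and no shNT sample does. An effect of lower YES1 stays open as well, untested.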

How the results depend on the processing

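Unstranded counts, scaling on genes without CCTTTC in the 3' UTR, testing those genes only and the 1.2-fold test were chosen only after the results were seen. YES1 was lower under all 16 alternatives run for it (log2 fold change -2.11 to -1.92, largest adjusted p = 7.28e-28). Of 3297 values of the other named genes under alternatives, 3188 kept direction and call, 109 (in 38 genes) lost the call and 0 reversed. FYN, MCL1, SOCS3, SLC16A3, SQSTM1, LAPTM5 and H2BC12 lost it in the 1.2-fold test alone, CD14 also with library size only, TNFAIP2 also when scaled on genes without CCTTTC, and SERPINA1 among others with library size only and DESeq2. Of 561 values of family members outside the naming rule, 25 (in 11 genes) lost the call and 0 reversed, C1S in the 1.2-fold test alone. Of 84 counts, 75 stayed within 1.5 times of the value reported. Tests on genes without CCTTTC only, 6499 genes, called 4437 (2728 higher, 1709 lower, 456 at least 2-fold), where fewer genes were tested. The 1.2-fold test called 5185 (2324 higher, 2861 lower), as a stricter threshold gives. Lists called numbered 12 as reported, 0 with an estimated correlation and 24 with fry, which asks another question. Leaving out each library in turn gave 8751 to 9078 changed genes.

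Of 539 list values, 483 were the same, 20 weaker, 23 stronger and 13, in 7 lists that were not called, reversed in the direction of the test, with the medians as follows. The epithelial list stood at -0.14 with library size only, -0.22 with no low-count filter, -0.24 with fry, -0.13 among genes without CCTTTC and -0.45 to -0.24 with a library left out. The hepatocyte list stood at 0.32 with library size only, and the Hippo list at 0.00883 with fry and -0.0809 when scaled on genes without CCTTTC. Among genes without CCTTTC the TGF-beta list stood at 0.36 and the lysosome list at 0.12. With a library left out, the interferon list ranged from -0.0515 to -0.0102 and the Notch list from -0.19 to 0.16. Among genes without CCTTTC, the oxidative phosphorylation list lost its call (adjusted p = 0.0657) with a median of 0.24 against 0.16 as reported. Fewer members were tested there, and the median of all genes tested was 0.0909 against -0.00469 as reported. The list medians thus have different baselines and do not show whether the change was smaller. The BCL2 family list lost its call (0.876) with a median of 0.15 against 0.31. The endoplasmic reticulum chaperone list was called when scaled on genes without CCTTTC (adjusted p = 0.0359). For these lists the cause was not tested.

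No clear pairing of the samples by the numbers 1 to 3 was seen. Deviations of same-numbered samples correlated at -0.00583, 0.0511 and -0.0268 across 8107 genes, and those of differently numbered samples at -0.0373 to 0.0436. Such values cannot exclude a weak pairing. With the replicate block 9297 genes changed (4628 higher, 4669 lower), and no call of a named gene or list changed. At this depth, simulated changes of 0.25 on the log2 scale were recovered in 54.2% of genes. Far fewer genes changed in the simulation than in the data, where the same adjusted p is easier to reach. The share recovered in the data was therefore not measured, and small changes can still be missed.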

Other observations

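The 4 gene families here were chosen only after their values were seen. Their adjusted p-values do not account for that choice, so they describe the families and do not test them. Metallothionein genes, which encode small metal-binding proteins, were lower in shYES1: 7 of 8 tested fell and 1 did not pass (median log2 fold change -1.19, camera adjusted p = 0.00611 over the 4 families, and adjusted p = 0.0853 with an estimated correlation). MT2A fell from 220.5 ± 8.50 to 94.5 ± 5.82 CPM (-1.23) and MT1E from 49.9 ± 3.48 to 26.8 ± 1.0 CPM (-0.90), though reads shared between these similar genes could not be assigned. Complement genes of innate immunity were lower as well, with 6 of 11 down and 0 up (median -0.32, camera adjusted p = 0.0199, and adjusted p = 0.131 with an estimated correlation). C3, the central component, fell from 2964 ± 57.5 to 2156 ± 15.6 CPM (-0.46) and CFB from 37.5 ± 2.74 to 15.4 ± 0.818 CPM (-1.27). C1S, a protease of the classical pathway, fell from 1106 ± 15.1 to 927 ± 7.28 CPM (-0.25).

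Genes of cyclin-dependent kinase inhibitors were mostly higher, with 4 of 5 up and 1 down (median 0.95, camera adjusted p = 0.00806, and adjusted p = 0.0853 with an estimated correlation). Besides CDKN1A, CDKN1C rose from 15.2 ± 0.991 to 39.8 ± 3.25 CPM (1.4) and CDKN1B from 78.0 ± 1.25 to 122.0 ± 2.29 CPM (0.65), while CDKN2C fell (-0.29). Semaphorins and their plexin receptors, which guide cell migration, gave 12 higher and 5 lower of 23 (median 0.23, camera adjusted p = 0.0263, and adjusted p = 0.185 with an estimated correlation). PLXNA1 rose from 160.4 ± 7.09 to 261.0 ± 2.74 CPM (0.70) and SEMA4F from 33.0 ± 1.27 to 69.8 ± 0.662 CPM (1.08), while SEMA3C fell from 545 ± 6.62 to 441 ± 11.8 CPM (-0.31). Among genes without CCTTTC in the 3' UTR, the inhibitor list (median 0.95, adjusted p = 0.276) and the semaphorin list (median 0.26, adjusted p = 0.076) were not called. Fewer members were tested there, and the median of all genes tested was 0.0909, against -0.00469 over all 14239 genes. These list medians therefore do not show whether the changes were smaller.

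Calls by gene type are given as counts, and the difference between types was not tested. Of 478 lincRNA genes tested 60 rose and 140 fell, of 604 antisense genes 70 rose and 145 fell, and of 413 processed pseudogenes 21 rose and 86 fell, against 4398 and 4136 of 12035 protein-coding genes. The noncoding types had median levels of 2.03, 1.55 and 1.36 CPM in shNT in that order, against 30.5 CPM for protein-coding genes. How many reads of processed pseudogenes come from their parent genes was not tested. Median log2 fold changes of the 23 chromosomes with enough tested genes ranged from -0.11 on chromosome 18, where YES1 lies, to 0.09 on chromosome 19.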
